A study of Mus musculus with 10 samples.

How the data were processed

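RNA from mouse kidney was measured by sequencing in 10 libraries. Per the labels, poly(A) RNA was turned into cDNA and into Illumina TruSeq libraries, and single-end reads of 100 bases were taken on an Illumina instrument. The labels name a different Qiagen column kit in the design text (RNeasy Mini) than in the extraction protocol (miRNeasy), and which of these was used is not settled here. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, Trim Galore, STAR 2.4.1d and HTSeq 0.6.1, with the build GRCm38; their settings, the annotation release and the strand setting are not given in the sources used here. The deposited values are raw counts of reads per gene, 1 table per library, for 46517 versioned Ensembl gene IDs, with no normalization by the authors. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart. Genes of near-identical families, such as immunoglobulin segments, Mup and Serpina3 genes, hemoglobins, Ugt1a exons and predicted genes with Gm names, can share reads with their copies, and their values are uncertain for that reason.

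Gene symbols and GRCm38 coordinates came from the GENCODE M21 annotation: 46005 of the 46517 IDs matched, 512 did not, and 118 IDs share a symbol with another. No column belonged to an unknown sample, and every count table named a gene in each of its lines. Library totals ran from 27596391 to 34815153 counts, so 3 counts, the floor used for a gene at 0, correspond to 0.0862 to 0.109 CPM (counts per 1000000) per library. Intervals and floors cover counting error only, since reads carried no molecular identifiers. Libraries were compared pairwise for repeat deposits: over genes with at least 50 counts, the lowest chi-square per gene of any pair was 26.2, so none of the 10 were alike within sampling noise.

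Groups were taken from the genotype label: G1 (n = 2), G2 (n = 2), wild type (single mutant) (n = 3) and Control (n = 3). Replicate numbers follow accession order and pair nothing. A total of 6 comparisons were made: the mean of G1 and G2 against Control and against wild type (single mutant), wild type (single mutant) against Control, G1 and G2 each against Control, and G2 against G1. The transcript of the human APOL1 transgene was not analysed here, so the genotype labels were not checked against the expressed gene.

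The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, and 1 quasi-likelihood fit with a mean per group over all 10 libraries, which share 1 estimate of the spread (common biological coefficient of variation 0.249). Of the 46517 genes, 17823 passed the filter. A gene was called, and is said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values with standard errors (SE) taken from the fold change and its quasi-likelihood F statistic; levels are CPM on TMM-scaled library sizes, given as mean ± SD. A gene with 0 counts throughout a group is given as a lower bound of its fold against 3 counts over that group, and one with 1 to 3 counts as a ratio with an exact 95% counting interval. Statistics in R were written with limma 3.58.1 and DESeq2 1.42.0 as alternatives; tables and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

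A total of 39 gene lists (988 symbols, of which 974 matched and 927 were tested) were fixed before the data were examined. They cover nephron segments and podocytes, other kidney cells, immune cells, injury, matrix, inflammation, interferon, autophagy, lysosome, metabolism, cell cycle, immediate early and clock genes, sex-biased genes, the mouse Apol family, and tissues that a dissection could carry along. Kidney was measured in bulk, so a list gives a level in the tissue and not a cell count. Changes within cells and changes in the cells present were not told apart. Lists were tested with camera on the fitted edgeR object (counts turned into z-scores under the negative binomial model) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists; camera with an estimated correlation and fry stand beside it. With the estimated correlation the tubular injury list is the 1 called in each of the comparisons of the risk alleles with Control and with wild type (single mutant), and in the comparison of G1 with Control; 1 list is called in wild type (single mutant) against Control, 5 in G2 against Control and 0 in G2 against G1. Counts of list members are given over all genes tested and adjusted over the list alone. The genes named follow a rule fixed at the same time: for each comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups compared (where fewer than 3 pass, the 3 with the lowest p are named as not passing); up to 4 members with the lowest p of each called list and of the podocyte, tubular injury, matrix, inflammasome and Apol lists; and a fixed set of podocyte, injury, inflammasome, autophagy and check genes. Of the genes under this rule the text names a part, and some results are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

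The scripts were tested on simulated data drawn with the real means and library sizes, over 17823 genes with 100 genes changed at each of 2 sizes. For the risk alleles against Control, 54% of genes changed 2-fold and 90% of those changed 4-fold were recovered, with 5 false calls. For G1 against Control these shares were 38% and 89% with 9 false calls, for wild type (single mutant) against Control 44% and 90% with 9, and for G2 against G1 22% and 77% with 5. In the real data 6653 genes were called for the risk alleles against Control. Shares found with few and balanced changes need not hold there.

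Alternatives fixed before the data were examined were DESeq2 size factors, no filter, a stricter filter of 1 CPM on average, DESeq2, limma voom with quality weights, leaving out each library, a term for Y-linked transcripts (summed CPM of 4 Y-linked genes above 10), a term for the letters that start the library titles (4 kinds, of which 3 each occur in 1 wild type (single mutant) library and in libraries of 1 other group), only the libraries of the groups compared, and both reference groups averaged. Scaling by library totals alone, a term for the 3 libraries whose titles have NA, and not NAP, before the number (NA titles), and a fit of the 7 other libraries were added after the data were seen. Only G1 replicate 2 lay below the cut for Y-linked transcripts, so that term acts as leaving this library out and is no separate adjustment for sex. No library was left out of the main test.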

Results

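Poly(A) RNA from mouse kidney was sequenced in 10 libraries, and reads were counted per mouse gene. The study addressed APOL1, a human gene of the apolipoprotein L family whose G1 and G2 alleles are known as risk alleles for kidney disease, by expressing its variants in podocytes, the epithelial cells that cover the glomerular filter. The labels give 4 groups: kidneys with the G1 allele (n = 2), with the G2 allele (n = 2), a group called wild type (single mutant) (n = 3) and Control (n = 3). The labels do not say what the words single mutant stand for. In units of 1000000 counts, the libraries held 34.2 and 33.9 for G1, 29.1 and 34.8 for G2, 31.35, 31.1 and 30.8 for wild type (single mutant), and 30.6, 29.5 and 27.6 for Control. Between 9.54% and 14.6% of the counts of a library lay in its 10 most abundant genes, and 4.88% to 8.92% in mitochondrial genes. The labels state neither the sex nor the age of the mice. They do not state that each library came from a separate mouse, so p-values measure the spread between these libraries. On the first principal component of log CPM, which held 52.6% of the variance, the 4 libraries with risk alleles scored from -104.27 to -36.71 and the 6 others from 38.81 to 60.62.

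The first comparison asks how kidneys with the APOL1 risk alleles (the mean of G1 and G2, 4 libraries) differed from Control (3 libraries). Genes of injured tubules were higher with the risk alleles. Lcn2 (ENSMUSG00000026822.13, GRCm38 chromosome 2, 32384633 to 32388252), which encodes the secreted siderophore-binding protein NGAL, was at 2.77 ± 0.729 CPM in Control (mean ± SD, n = 3), 285 ± 95.8 in G1 (n = 2) and 159.9 ± 57.6 in G2 (n = 2). Its log2 fold change was 6.26 ± 0.34 (SE). Havcr1 (chromosome 11, 46735080 to 46779578), the tubular injury marker KIM-1, was at 2.85 ± 0.653 CPM in Control, 324 ± 79.3 in G1 and 104 ± 69.2 in G2, a log2 fold change of 6.01 ± 0.47. The chemokine gene Ccl2 rose by 5.17 ± 0.37 on the log2 scale and the adhesion molecule gene Vcam1 by 4.58 ± 0.35. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 2.88e-05 for Lcn2, 7.88e-05 for Havcr1, 6.25e-05 for Ccl2 and 7.05e-05 for Vcam1. Each of these genes was higher in all 4 libraries than in any Control library. Of the 40 genes of the tubular injury list, 36 rose, 0 fell and 4 were not called (37 and 0 adjusted over the list alone). The median log2 fold change was 2.56. The list passed in camera with an adjusted p of 3.58e-33, and with an adjusted p of 0.0336 when the correlation was estimated.

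Genes of fibroblasts and extracellular matrix rose with the injury genes. Col1a1 (chromosome 11, 94936224 to 94953042), a chain of type I collagen, was at 31.4 ± 6.4 CPM in Control, 162 ± 41.6 in G1 and 379 ± 127 in G2, a log2 fold change of 2.98 ± 0.30 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000168). The membrane-bound metalloproteinase gene Mmp14 rose by 2.86 ± 0.22, the collagen-crosslinking enzyme gene Loxl2 by 2.56 ± 0.13, the intermediate filament gene Vim by 2.12 ± 0.19 and the basement membrane collagen gene Col4a1 by 1.86 ± 0.18. Of 43 genes in the list, 35 rose, 0 fell and 8 were not called (36 and 0 adjusted over the list alone). In camera the adjusted p was 4.46e-22, and adjusted p = 0.0733 with an estimated correlation. Cell cycle genes were higher as well: 35 of 38 rose, 1 fell and 2 were not called (35 and 1 adjusted over the list alone), with a median log2 fold change of 2.73. Among them the proliferation marker Mki67 went from 3.34 ± 0.204 CPM in Control to 68.1 ± 13 in G1 and 28.2 ± 11.1 in G2, and Top2a, which encodes a topoisomerase used in mitosis, rose by 3.38 ± 0.17. With camera the adjusted p was 3.3e-47, and adjusted p = 0.0733 with an estimated correlation.

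**Figure D1:**
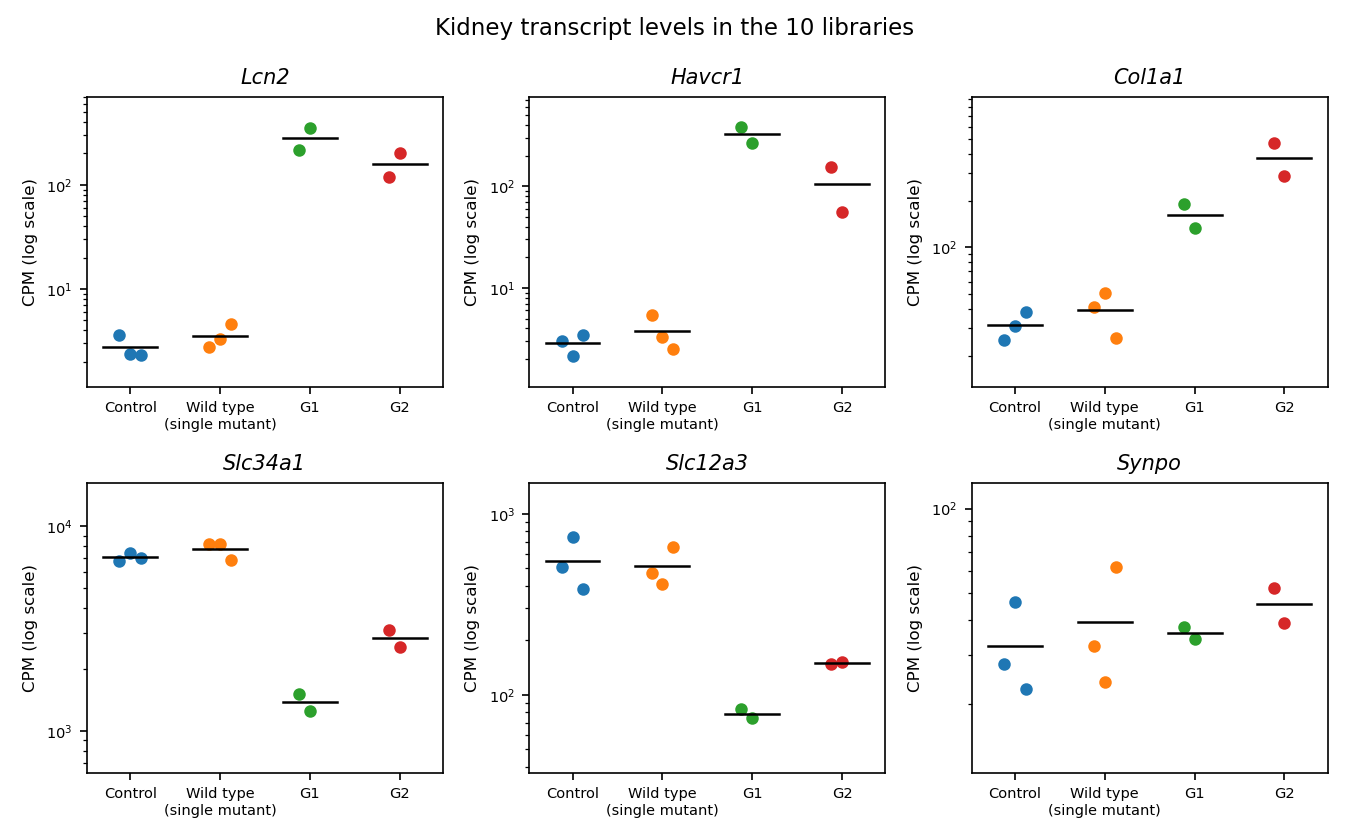
CPM (log scale) of 6 genes in the 10 libraries, 1 point per library, with a line at the mean of each group. Lcn2, Havcr1 and Col1a1 lie higher in the G1 and G2 libraries than in the Control and wild type (single mutant) libraries, Slc34a1 and Slc12a3 lie lower, and the Synpo values of G1 and G2 lie within the range of the wild type (single mutant) libraries.

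Lists of the proximal tubule, the distal convoluted and connecting tubule and intercalated cells were downward, whereas those of the thick ascending limb and of collecting duct principal cells were not called (camera adjusted p = 0.166 and 0.185). Slc34a1 (chromosome 13, 55398187 to 55415592), the phosphate transporter of the proximal tubule, was at 7076 ± 318 CPM in Control, 1379 ± 182 in G1 and 2845 ± 396 in G2, a log2 fold change of -1.84 ± 0.15 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.94e-05). Lrp2, the endocytic receptor megalin, fell with a log2 fold change of -1.53 ± 0.11, and Fbp1, an enzyme of gluconeogenesis, with -1.40 ± 0.11. Of the 30 genes of the first proximal tubule segments (S1 and S2) 29 fell and 1 was not called (30 fell adjusted over the list alone). The camera adjusted p was 2.95e-25, and adjusted p = 0.0589 with an estimated correlation. The list of the third segment (S3) had 16 genes, of which 6 fell, 1 rose and 9 were not called (7 and 1 adjusted over the list alone). In it the cystine and aspartate carrier gene Slc7a13 fell with a log2 fold change of -3.40, while Slc5a1, a glucose transporter gene, rose by 1.05. By camera this list had an adjusted p of 0.000809, and an adjusted p of 0.153 with an estimated correlation. With each allele alone against Control, 8 of the 16 S3 genes fell and 1 rose in G1, and 2 fell and 1 rose in G2. The S3 list was not called in G2 (camera adjusted p = 0.193). Slc12a3, the thiazide-sensitive salt transporter, went from 546 ± 183 CPM in Control to 78.7 ± 6.35 in G1 and 149.8 ± 2.47 in G2. The calcium-binding protein gene Pvalb fell with a log2 fold change of -3.33 ± 0.35. Of the 17 genes of the distal convoluted and connecting tubule 15 fell and 2 were not called (15 adjusted over the list alone). Its camera adjusted p was 1.68e-09, and adjusted p = 0.219 with an estimated correlation. Of 20 intercalated cell genes, 11 fell, among them the proton pump subunit gene Atp6v0a4 (-1.07 ± 0.08), 1 rose and 8 were not called (11 and 1 adjusted over the list alone). Tested with camera, the list had adjusted p = 5.2e-05, and adjusted p = 0.445 with an estimated correlation.

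Lists of macrophages, neutrophils, T and NK cells and NF-kB signalling were upward, whereas that of B and plasma cells, with 2 rises and 5 falls among 22 genes, was not called (camera adjusted p = 0.756). Cd14, a receptor for bacterial lipopolysaccharide, went from 7.75 ± 1.15 CPM in Control to 119.5 ± 58 in G1 and 70.3 ± 2.16 in G2, and the lysozyme gene Lyz2 rose by 3.20 ± 0.28 on the log2 scale. Of 32 macrophage and dendritic cell genes, 29 rose, 0 fell and 3 were not called (29 and 0 adjusted over the list alone). Camera gave an adjusted p of 2.89e-19, and an adjusted p of 0.103 with an estimated correlation. Of 33 T and NK cell genes 16 rose and 17 were not called (20 rose adjusted over the list alone), among them the chemokine gene Ccl5 (4.07 ± 0.57) and the coreceptor gene Cd4 (2.26 ± 0.35). Its camera adjusted p was 1.21e-05, and adjusted p = 0.445 with an estimated correlation. In the neutrophil list, 9 of 13 genes rose, 1 fell and 3 were not called (9 and 2 adjusted over the list alone), with Csf3r, the receptor of the growth factor G-CSF, at 1.85 ± 0.31. Its camera adjusted p was 0.00744, and adjusted p = 0.304 with an estimated correlation. The list of NF-kB and cytokine signalling had 37 genes that rose, 2 that fell and 5 not called of 44 (38 and 3 adjusted over the list alone). Relb, a subunit of the transcription factor NF-kB, rose by 2.64 ± 0.18 and Csf1, the growth factor of macrophages, by 2.55 ± 0.17. Tested with camera, the list had adjusted p = 3.87e-28, and adjusted p = 0.0733 with an estimated correlation. These lists share genes with each other and with the tubular injury list, so their calls are not separate lines of evidence. Cd14 is also on the injury list, as is Lcn2 of the neutrophil list. Ccl5 is also on the NF-kB list, and Ccl2 and Vcam1 are on the injury and NF-kB lists. Each list is a level in the tissue and not a cell count, as are the lists of tubule segments and of metabolism.

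Pyroptosis and the inflammasome are processes that have been linked to APOL1 risk alleles, and 16 of the 26 genes of that list rose, 2 fell and 8 were not called (18 and 2 adjusted over the list alone). Panx1, a channel for ATP release, rose by 2.63 ± 0.21, Mlkl, the membrane-permeabilizing protein of necroptosis, by 2.60 ± 0.29, and its activating kinase Ripk3 by 2.08 ± 0.22. Nlrp3, the sensor of the inflammasome, was at 0.674 ± 0.276 CPM in Control, 2.93 ± 0.626 in G1 and 2.02 ± 0.356 in G2, a log2 fold change of 1.84 ± 0.34 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0032). Casp1, the protease it activates, and the cytokine gene Il1b were not called. Their log2 fold changes were 1.02 ± 0.36 and 1.53 ± 0.64, with adjusted p of 0.0533 and 0.0926 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The list had a camera adjusted p of 2.61e-06, and an adjusted p of 0.0886 with an estimated correlation. Complement had 14 genes that rose, 4 that fell and 11 not called of 29 (14 and 4 adjusted over the list alone). The central component C3 went from 49.6 ± 12.2 CPM in Control to 2838 ± 96.4 in G1 and 509 ± 225 in G2, while C8a, a chain of the membrane attack complex, fell with a log2 fold change of -2.26 ± 0.22. Camera gave an adjusted p of 0.000334, and an adjusted p of 0.0853 with an estimated correlation. Of 46 interferon response genes 27 rose and 19 were not called (28 adjusted over the list alone), among them the antiviral gene Oas1a (1.88 ± 0.21) and the transcription factor gene Irf7 (1.63 ± 0.20). In camera the adjusted p was 7.43e-08, and adjusted p = 0.374 with an estimated correlation. Of 24 antigen presentation genes 4 rose and 20 were not called (1 adjusted over the list alone). Tested with camera, the list had adjusted p = 0.0169, and adjusted p = 0.715 with an estimated correlation. Its member Tapbp, a peptide-loading chaperone, rose by 0.73 ± 0.13, whereas the calls of H2-Aa (1.55 ± 0.53), H2-K1 and the peptide transporter gene Tap2 were each lost without G1 replicate 1, G1 replicate 2, G2 replicate 1 or Control replicate 1, among others. Of 21 immediate early genes, 9 rose, 1 fell and 11 were not called (9 and 1 adjusted over the list alone), with the cytokine signalling inhibitor Socs3 at 3.34 ± 0.29. In camera the adjusted p was 0.00401, and adjusted p = 0.374 with an estimated correlation. With each allele alone against Control, 10 immediate early genes rose and 0 fell in G1, and 3 rose and 2 fell in G2. Antigen presentation had 6 rises in G1 and 0 in G2. Neither list was called in G2 (camera adjusted p = 0.221 for immediate early genes and 0.0953 for antigen presentation).

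Podocytes are the cells in which APOL1 was expressed, and their 37 tested marker genes did not move one way: 8 rose, 6 fell and 23 were not called, with the same counts adjusted over the list alone. The intermediate filament gene Nes went from 21.1 ± 3.25 CPM in Control to 91.2 ± 1.06 in G1 and 62.6 ± 14.5 in G2 (1.84 ± 0.20), and Cd2ap, an adapter of the slit diaphragm, rose by 0.85 ± 0.12. Nphs1 (chromosome 7, 30458315 to 30487223), which encodes nephrin of the slit diaphragm, was not called at -0.87 ± 0.48, nor was Podxl, a surface sialomucin gene, at -0.20 ± 0.28, the actin-binding protein gene Synpo at 0.33 ± 0.34 or the transcription factor gene Wt1 at 0.70 ± 0.41. Their adjusted p ran from 0.187 (Nphs1) to 0.606 (Podxl) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nphs1 varied from 5.89 to 22.4 CPM between the 3 Control libraries. The list's median log2 fold change was -0.04 (0.215 with library totals alone), its mean 0.03, and its camera direction upward with an adjusted p of 0.756 (0.918 as adjusted p with an estimated correlation).

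The lists of fatty acid oxidation and oxidative phosphorylation were downward. Of 38 genes of fatty acid oxidation 21 fell and 17 were not called (22 adjusted over the list alone), among them Acadvl, the very long chain acyl-CoA dehydrogenase (-1.14 ± 0.11), and Hadhb, a subunit of the trifunctional protein (-1.09 ± 0.09). The camera adjusted p was 1.18e-09, and adjusted p = 0.0733 with an estimated correlation. Of 56 genes of oxidative phosphorylation 39 fell and 17 were not called (41 adjusted over the list alone), among them the ATP synthase subunit gene Atp5b (-1.11 ± 0.11) and Sdha of complex II (-1.11 ± 0.09). The camera adjusted p was 1.43e-11, and adjusted p = 0.374 with an estimated correlation. Cholesterol synthesis had 11 genes that fell and 13 not called of 24 (11 adjusted over the list alone), with the isomerase gene Idi1 at -1.90 ± 0.26 and the demethylase gene Cyp51 at -1.48 ± 0.26. In camera the adjusted p was 0.0043, and adjusted p = 0.214 with an estimated correlation. In the unfolded protein response list 9 of 28 genes fell, 2 rose and 17 were not called (11 and 2 adjusted over the list alone), with the chaperone gene Hyou1 at -0.98 ± 0.15. The camera adjusted p was 0.00744, and adjusted p = 0.551 with an estimated correlation. Autophagy had 14 genes that fell, 4 that rose and 29 not called of 47 (the same adjusted over the list alone), with the mitophagy kinase Pink1 at -1.10 ± 0.13 among the falls and the E1-like enzyme Atg7 at 0.62 ± 0.08 among the rises. The autophagy receptor gene Sqstm1 (-0.16 ± 0.12) and the marker gene Map1lc3b (-0.04 ± 0.08) were not called. The camera adjusted p of autophagy was 0.0456, with an adjusted p of 0.374 at an estimated correlation. With libraries scaled by their totals alone the autophagy counts turned to 12 higher and 5 lower, its median from -0.16 to 0.11, and its call was lost (camera adjusted p = 0.357). The upward calls of neutrophils (median 1.79, camera adjusted p = 0.0709) and of antigen presentation (median 1.07, 0.129) were lost as well, and clock genes (0.0257), female-biased genes (0.0137) and adipose (0.00349) gained a downward one. Under the same scaling the counts of higher and lower genes were 5 and 5 for the unfolded protein response and 3 and 4 for cholesterol synthesis, whose medians stayed below 0.

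**Figure D2:**
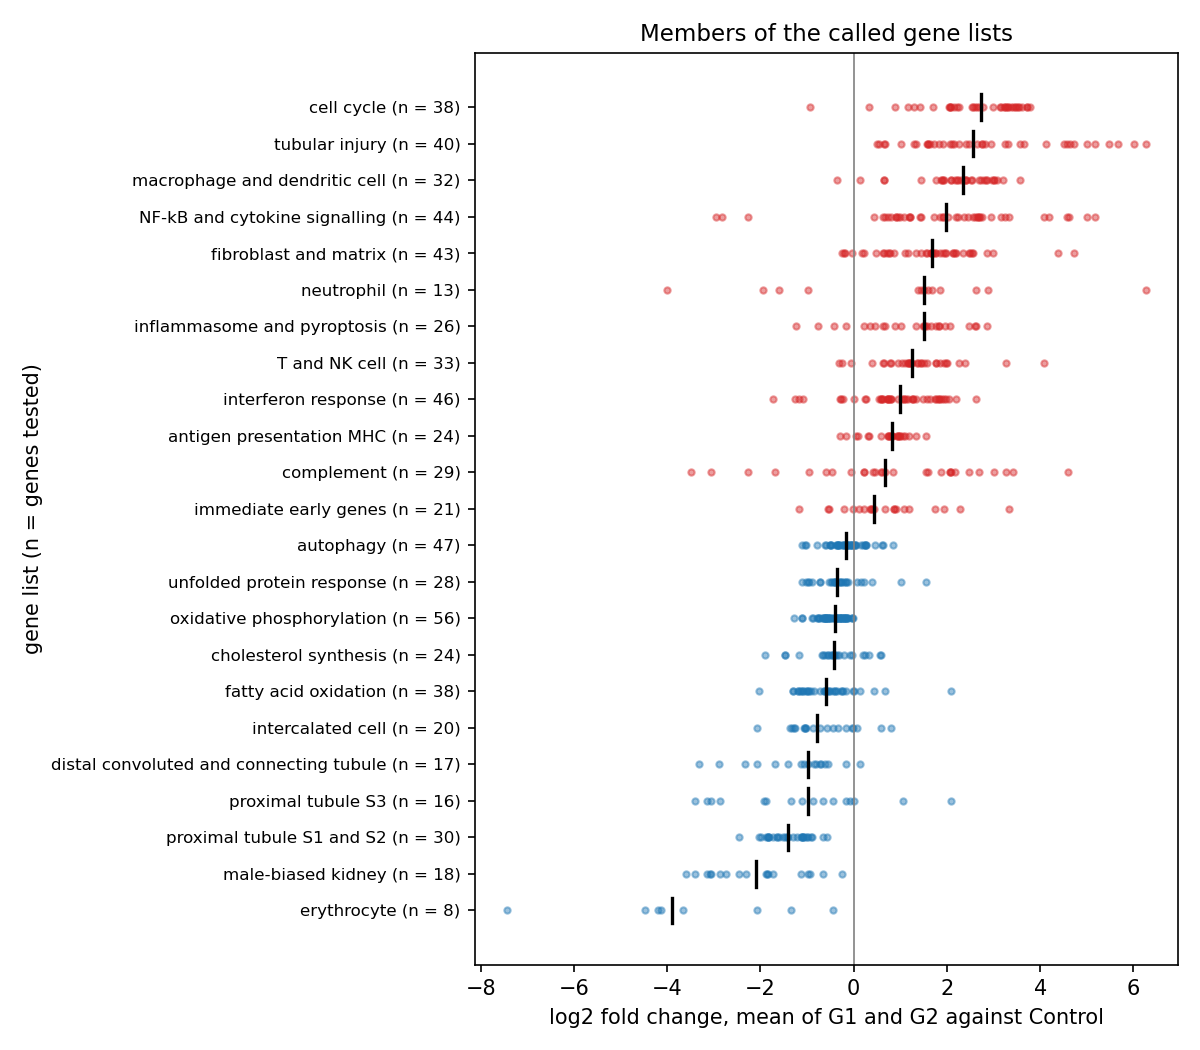
Log2 fold changes (horizontal axis) of the tested members of the 23 lists called by camera, mean of G1 and G2 against Control; each point is 1 gene and each black bar the list's median. Medians run from -3.90 for the erythrocyte list to 2.73 for the cell cycle list, and that of the autophagy list, -0.16, changes sign with scaling by library totals alone.

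The erythrocyte and male-biased kidney lists were downward as well, and the female-biased list was not called (camera adjusted p = 0.0773). All 8 tested erythrocyte genes fell (8 adjusted over the list alone): the hemoglobin gene Hbb-bs went from 354 ± 114 CPM in Control to 5.86 ± 0.62 in G1 and 69.2 ± 36.9 in G2, and Alas2, the erythroid enzyme of heme synthesis, fell with a log2 fold change of -4.48 ± 0.31. Hemoglobin genes can share reads with their copies. For these genes the camera adjusted p was 3.43e-12, and adjusted p = 0.0746 with an estimated correlation. Of 18 male-biased kidney genes 15 fell and 3 were not called (15 adjusted over the list alone). A proximal tubule list also holds 7 of them, of which 6 fell, and of the 11 others 9 fell, among them Cyp4b1, a cytochrome P450 gene, from 5357 ± 452 CPM in Control to 410.3 ± 288 in G1 and 1566 ± 118 in G2. By camera this list had an adjusted p of 3e-10, and an adjusted p of 0.134 with an estimated correlation. The calls lay mostly in G1: against Control, 15 of the 18 fell in G1 (median -3.54) and 2 in G2 (median -0.92). Adjusted over the list alone these counts were 16 and 2. In G2 the camera adjusted p was 0.00155, and adjusted p = 0.516 with an estimated correlation. G1 replicate 2 had 0.202 CPM of the Y-linked gene Ddx3y and 359.7 CPM of Xist, the RNA of the inactive X chromosome, while the other 9 libraries had 36.1 to 51.7 CPM of Ddx3y and at most 1.13 CPM of Xist. Without G1 replicate 2, 12 of the 18 male-biased genes fell. Camera left 16 lists without a call. Of nephron and kidney cells these were podocytes (above), thick ascending limb (2 rose and 7 fell of 17), collecting duct principal cells (1 and 3 of 17), endothelium (2 and 3 of 26), and mesangium and smooth muscle (6 and 0 of 19). The others were B and plasma cells (2 and 5 of 22), lysosome (9 and 15 of 53, or 21 and 5 with library totals alone, which turn its median from -0.09 to 0.185), clock genes (0 and 4 of 19), female-biased genes (1 and 6 of 13), Y-linked genes and Xist (0 and 0 of 5), adrenal (1 and 0 of 5), adipose (0 and 2 of 15), urothelium (1 and 0 of 12), skeletal muscle (1 and 2 of 6), pancreas and liver (2 and 2 of 10) and the mouse Apol family. Adjusted over the list alone the counts were the same except for endothelium (1 and 2), clock genes (0 and 3) and pancreas and liver (3 and 3). The camera adjusted p of these 16 lists ran from 0.0636 (adipose) to 0.856 (adrenal). None of the 4 Apol genes tested was called, with log2 fold changes from -2.32 for Apol6 to 0.06 for Apol9b. Median and mean differed in sign for the podocyte list (above), the lysosome list (-0.09 and 0.02), the adrenal list (-0.05 and 0.47) and the list of Y-linked genes and Xist (-0.30 and 0.50).

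By the rule on size, the 10 rises included genes almost absent from Control. Spaca7, an acrosome protein gene, had 467 counts over the 4 libraries with risk alleles and 0 in Control, at least 85.4-fold higher against 3 counts over the group, and D630011A20Rik, whose annotated span overlaps that of Spaca7, had 515 and 3 counts. The ratio was 94.1 (95% counting interval 32 to 458) for D630011A20Rik, 266 (47.5 to 10500) for the chemokine gene Cxcl17, 267 (91.3 to 1300) for Il1f6, a cytokine gene of the interleukin-1 family, 206 (36.7 to 8140) for Arhgap36 and 215 (59.2 to 1780) for Sprr2f, an epithelial envelope gene. Saa1, an acute phase protein gene, rose by 6.42 ± 0.62 and the transferrin family gene Meltf by 6.14 ± 0.54; Lcn2 and Havcr1 complete the 10. Of the 10 falls, 7 were immunoglobulin segments or a hemoglobin gene with shared reads. Ighv1-72 was at least 169-fold lower, and Igkv3-10, with 0 counts in G1, at least 157-fold lower there. Mean CPM in Control and with the risk alleles were 4.13 and 0.025 for Ighv3-6, 3.44 and 0.0602 for Igkv3-2, 9.62 and 0.209 for Igkv8-21, and 2.99 and 0.0596 for Ighv1-82. Of Control, replicates 1 and 2 have the letters NA in their titles, as has wild type replicate 3 but no library with risk alleles, and among the 6 reference libraries 15 immunoglobulin genes were higher with such titles and 0 lower. The summed CPM of immunoglobulin genes was 555 and 1746 in Control replicates 1 and 2, 647 in replicate 3 and 1004 in wild type replicate 3, against 30.8 and 84.8 in the other wild type libraries and 48.1 to 319.8 with the risk alleles. Of 112 immunoglobulin genes tested 65 fell, and with a term for NA titles 27 were lower and 2 higher. That term ended the calls of Ighv1-82 (log2 fold change -2.80) and Igkv3-2 (-3.49), and the latter was lost without Control replicate 2 as well (-4.44). The log2 fold change of Hba-a2 was -7.44 ± 2.45. Hba-a2 stood at 98.8 CPM in Control replicate 1 and at 0.942 and 0.676 in the others, and its call was lost without that library or without any 1 of the G1 and G2 libraries. The liver genes Mup3 and Serpina3k had 1 count each with the risk alleles, 109-fold (18.9 to 4390) and 102-fold (17.6 to 4110) lower. Either call was lost without G1 replicate 2, G2 replicate 1 or 2, or Control replicate 3. Hrg, a plasma glycoprotein gene, fell from 7.22 ± 2.58 CPM in Control to 0.905 ± 0.328 in G2 and 0 counts in G1, at least 190-fold lower in G1 against 3 counts over the group.

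Over all genes, 6653 of the 17823 tested (37.3%) were called in this comparison, 3441 higher and 3212 lower, of which 1769 and 1066 by more than 2-fold. With libraries scaled by their totals alone, 7637 were called and the share of higher calls went from 51.7% to 79.05%, with the median log2 fold change of all genes at 0.28. Fold changes above are relative to a median of 0.00 under TMM. With a term for the letters that start the library titles the count fell to 1811, and with the 7 libraries without NA titles, where 1 Control library remains, it was 4216. The fold changes of the called genes were then at a median of 1.08 and 1.07 times their size, and their median SE went from 0.165 to 0.289 and 0.211. The genes were called with all libraries, so such ratios, here and below, are no independent check of the fold changes. The term for title letters is nearly aligned with the groups, and no library with risk alleles shares the NA titles of Control replicates 1 and 2. It therefore separates letters from genotype only with low precision in this comparison. A part of these changes that follows the title letters stays open.

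The second comparison set the risk alleles against the wild type (single mutant) libraries (4 against 3), which asks whether the difference from Control recurs against the other reference. Lcn2 rose by 5.90 ± 0.34 on the log2 scale, from 3.58 ± 0.923 CPM in wild type (single mutant), and Havcr1 by 5.62 ± 0.46, from 3.74 ± 1.5 CPM. Ccl2 rose by 6.15 ± 0.40 and Col1a1 by 2.65 ± 0.29. Slc34a1 fell from 7735 ± 777 CPM, with a log2 fold change of -1.97 ± 0.15. Adjusted p were 3.38e-05 for Lcn2, 8.07e-05 for Havcr1, 3.49e-05 for Ccl2, 0.000232 for Col1a1 and 6.76e-05 for Slc34a1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the inflammasome genes, Nlrp3 (2.41 ± 0.35), Casp1 (1.34 ± 0.37) and Il1b (2.19 ± 0.68) rose. The call of Casp1 was lost without wild type replicate 1, and that of Il1b without G1 replicate 2, G2 replicate 1, or wild type replicates 1 or 2. Casp4, the caspase that senses cytosolic lipopolysaccharide, rose by 3.23 ± 0.38. Nphs1 fell with a log2 fold change of -1.52 ± 0.48 and an adjusted p of 0.033 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This call was lost without any 1 of the G1 or G2 libraries or without wild type replicate 1 or 3. Podxl (-0.60 ± 0.28), Synpo (0.04 ± 0.34) and Wt1 (0.14 ± 0.40) were not called.

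Against wild type (single mutant), 39 of the 40 tubular injury genes rose and 0 fell (the same adjusted over the list alone). By camera this list had an adjusted p of 2.87e-37, and an adjusted p of 0.0362 with an estimated correlation. Immediate early genes, which are induced within minutes of a stimulus, had 18 of 21 that rose and 0 that fell (18 adjusted over the list alone), with Egr2 at 4.22 ± 0.43 and Jun at 1.88 ± 0.20. Camera gave an adjusted p of 7.71e-11, and an adjusted p of 0.0839 with an estimated correlation. The wild type (single mutant) libraries were themselves lower in these genes than Control, with a list median of -0.993. Antigen presentation had 16 of 24 that rose (18 adjusted over the list alone), among them H2-Aa (2.87 ± 0.56) and H2-K1 (1.90 ± 0.34). Its camera adjusted p was 5.84e-05, and adjusted p = 0.53 with an estimated correlation. Of the thick ascending limb genes 7 of 17 fell and 1 rose (the same adjusted over the list alone), with the growth factor gene Egf at -1.56 ± 0.17 and the tight junction gene Cldn16 as the rise at 1.51 ± 0.13. By camera this list had an adjusted p of 0.0425, and an adjusted p of 0.581 with an estimated correlation. In total 23 lists were called, 12 upward and 11 downward, and 22 of them were also called against Control. The unfolded protein response list was called against Control alone (camera adjusted p here 0.547) and the thick ascending limb list here alone. The difference between these comparisons is that of wild type (single mutant) against Control, tested below. There camera placed the unfolded protein response lower (median -0.236, adjusted p 3.26e-10) and the thick ascending limb higher (median 0.195, adjusted p 0.0194). With an estimated correlation the camera adjusted p were 0.356 and 0.649, so neither list kept its call.

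The 10 rises by the rule on size were Sprr2f, at least 151-fold higher against 3 counts, Il1f6, Ccl20, Areg, Arhgap36 and Spaca7 with 1 to 3 counts in the reference, the acute phase gene Orm2 (6.82 ± 0.88), the interleukin-1 antagonist Il1rn (6.44 ± 0.54), Ccl2 and Timp1 (6.07 ± 0.60), an inhibitor of metalloproteinases. The ratio was 423 (95% counting interval 117 to 3490) for Il1f6, 220 (75.1 to 1070) for the chemokine gene Ccl20, 236 (42.2 to 9360) for Areg, a ligand of the EGF receptor, 108 (29.8 to 898) for Arhgap36 and 89.9 (30.6 to 438) for Spaca7. Most of the 10 falls were genes known from liver: Serpina3k, Mup3, Mup10, Ahsg, Cyp3a11, Ces1c, Cps1 and Alb, joined by Spink6 and Nccrp1. The fixed pancreas and liver list had 5 falls and 1 rise among 10 genes (the same adjusted over the list alone) and was not called. Its camera adjusted p was 0.115, and adjusted p = 0.581 with an estimated correlation. Alb, which encodes albumin, was at 199 CPM in wild type replicate 1, 8.73 and 22.1 in the other wild type libraries, and 0.551 to 1.77 with the risk alleles (-6.29 ± 1.02). Spink6, an inhibitor of kallikreins, lost its call without wild type replicate 3 among other libraries. A total of 7120 genes were called, 3680 higher and 3440 lower, of which 1983 and 1163 by more than 2-fold. Scaling by library totals alone called 7936 genes and moved the higher share from 51.7% to 78.45%. It ended the call of the autophagy list (median -0.21, or 0.07 with totals alone, camera adjusted p = 0.176), while clock, female-biased, adipose, and pancreas and liver genes gained a downward one. With the scaling of the other comparisons, 2990 higher and 2764 lower calls were shared with the comparison against Control and 0 were opposite, where independent lists would share 710.5 and 619.9. Both comparisons use the same 4 libraries with risk alleles, and unchanged groups simulated with that overlap shared 0 and 0 on average over 20 simulations. As almost no unchanged gene passes the threshold, that count was nearly fixed in advance and does not show what the shared libraries add. The covariance of the fold changes across genes was 1.09 (0.0731 in the simulation, a difference of 1.017) and their correlation 0.905 (0.438 in the simulation).

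The third comparison set wild type (single mutant) against Control (3 against 3), the reference groups against each other. No gene was called in edgeR's quasi-likelihood test (the lowest Benjamini-Hochberg adjusted p was 0.165); 724 genes had an unadjusted p under 0.05, DESeq2 called 14 and limma voom 0. Kirrel2 (chromosome 7, 30447534 to 30457690), a member of the nephrin-like adhesion molecules, was at 0.21 ± 0.0426 CPM in wild type (single mutant) and 5.66 ± 3.42 in Control, a log2 difference of -4.73 ± 0.53 that did not pass. Its values in the 3 libraries of either group did not overlap, a separation that chance gives 10% of genes. The nuclear receptor gene Nr4a1 was at 3.21 ± 0.355 and 15.2 ± 6.47 CPM (-2.24 ± 0.28), and the immunoglobulin light chain segment Iglv2 had 2 counts against 98, a ratio of 51.6 (95% counting interval 13.9 to 432) with reads that its copies can share. These 3 genes shared the adjusted p of 0.165 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Kirrel2 and Nr4a1 were called with DESeq2 and without a low-count filter, Kirrel2 without Control replicate 3, and Nr4a1 without Control replicate 1. In the upward direction the 3 lowest p belonged to Grid1 (1.85 ± 0.37), 4930452B06Rik (1.12 ± 0.23) and Acss3 (0.96 ± 0.20), which did not pass either.

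The immediate early genes were lower as a list in wild type (single mutant) than in Control. Fos was at 0.921 ± 0.121 CPM against 6.12 ± 5.04, and Egr1 at 4.29 ± 1.16 against 20.2 ± 10.5. Of the 21 genes 0 were called over all genes, and 13 were lower adjusted over the list alone. The list had a median of -0.99, a camera adjusted p of 7.49e-40, an adjusted p of 0.0314 with an estimated correlation and a fry adjusted p of 0.138. Camera called 18 lists, 5 upward and 13 downward, of which this one kept its call with an estimated correlation, and fry called 0. Next by camera were macrophages (median -0.58, adjusted p 1.51e-11, and an adjusted p of 0.356 with an estimated correlation) and the unfolded protein response (median -0.24, adjusted p 3.26e-10, and an adjusted p of 0.356 with an estimated correlation). Larger medians than these belonged to antigen presentation (-1.03), skeletal muscle (-1.17), adipose (-1.02) and erythrocytes (-0.85), with 0 members called over all genes or over the list alone. Their camera adjusted p were 1.17e-09, 0.00331, 0.015 and 2.11e-06, and with an estimated correlation the adjusted p were 0.525, 0.295, 0.73 and 0.356. The pancreas and liver list was upward, with a median of 1.63 and 5 of 10 higher adjusted over the list alone. In camera the adjusted p was 0.000558, and adjusted p = 0.376 with an estimated correlation. Its member Ttr, the thyroid hormone carrier, was at 400 and 314 CPM in wild type replicates 1 and 2 and 3.17 in replicate 3. The podocyte list had a median of 0.18 and a camera adjusted p of 0.00528, and an adjusted p of 0.649 with an estimated correlation. In it Nphs1 stood at 0.65 ± 0.52, and of the injury genes Lcn2 stood at 0.37 ± 0.31 and Havcr1 at 0.40 ± 0.43, none of them called. The tubular injury list as a whole went the other way, with a median of -0.318 and 0 of 40 members called. Its camera adjusted p was 2.83e-07, and adjusted p = 0.356 with an estimated correlation.

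**Figure D3:**
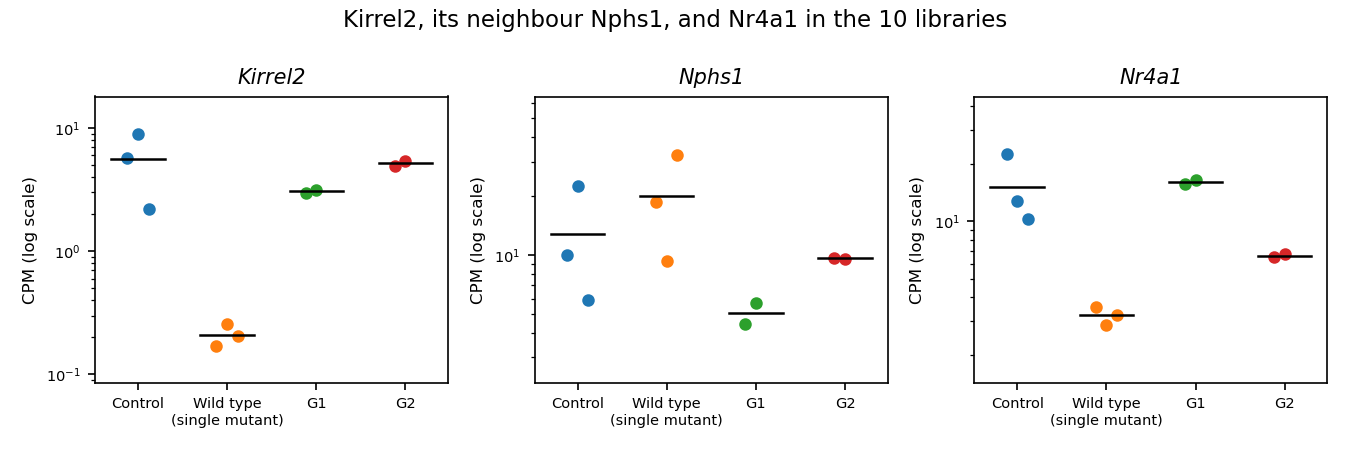
CPM (log scale) of Kirrel2, of Nphs1, its neighbour on chromosome 7, and of Nr4a1 in the 10 libraries, 1 point per library, with a line at the mean of each group. Kirrel2 lies between 0.171 and 0.256 CPM in the wild type (single mutant) libraries and between 2.19 and 9.02 CPM in the others, while the Nphs1 values of wild type (single mutant) and Control overlap.

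The alleles were also each compared with Control. In G1 (2 against 3 libraries), Lcn2 rose by 6.68 ± 0.36 on the log2 scale, Havcr1 by 6.83 ± 0.51, C3 by 5.84 ± 0.33, Col1a1 by 2.37 ± 0.32 and Krt20, a keratin of surface epithelia, by 7.24 ± 0.59. Krt20 went from 1.12 ± 0.605 CPM in Control to 169 ± 6.83 in G1. Slc34a1 fell with a log2 fold change of -2.36 ± 0.19 and Slc12a3 with -2.80 ± 0.31. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of these genes ran from 2.14e-05 (Lcn2) to 0.000629 (Col1a1). Spaca7 was at least 119-fold higher and Hrg at least 190-fold lower, each against 3 counts over the group at 0. Of the endothelial genes 12 of 26 fell and 2 rose (15 and 2 adjusted over the list alone), among them the VEGF receptor gene Kdr (-1.55 ± 0.33). Tested with camera, the list had adjusted p = 0.00171, and adjusted p = 0.598 with an estimated correlation. Xist was higher (8.97 ± 1.80), carried by G1 replicate 2. A total of 6656 genes were called, 3472 higher and 3184 lower. With library totals alone the share of higher calls moved from 52.2% to 76.3%. Without G1 replicate 1 or 2 the count was 4113 or 3397, with a term for Y-linked transcripts 3390, and with a term for title letters 1449. In the same order the fold changes of the called genes had a median of 1.03, 0.969, 0.967 and 1.003 times their size, and their median SE went from 0.198 to 0.256, 0.256, 0.255 and 0.335.

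In G2 (2 against 3 libraries), Lcn2 rose by 5.85 ± 0.35, Havcr1 by 5.19 ± 0.48, Col1a1 by 3.59 ± 0.33 and Col12a1, a fibril-associated collagen, by 2.56 ± 0.19. Slc5a12, a lactate transporter of the proximal tubule, fell with a log2 fold change of -2.56 ± 0.22 and the nuclear receptor gene Ppara with -2.83 ± 0.37. Adjusted p ran from 0.000189 (Lcn2) to 0.00169 (Ppara) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In this comparison 5 lists were called with an estimated correlation: proximal tubule S1 and S2 (24 of 30 fell), matrix (35 of 43 rose), tubular injury (32 of 40 rose), complement (16 rose and 2 fell of 29) and fatty acid oxidation (17 of 38 fell). Adjusted over the list alone, these counts were 28, 36, 34, 16 and 2, and 22, and the camera adjusted p with an estimated correlation was 0.0408 for each. Genes of mesangial cells, pericytes and smooth muscle had 9 of 19 that rose and 0 that fell (11 adjusted over the list alone), among them the pericyte receptor gene Pdgfrb (1.64 ± 0.27). Camera gave an adjusted p of 0.000863, and an adjusted p of 0.484 with an estimated correlation. Of the 37 podocyte genes 7 rose, 3 fell and 27 were not called (the same adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.319. Among the rises was the transcription factor gene Tcf21 (1.98 ± 0.27). Foxj1, the regulator of motile cilia, rose by 5.40 ± 0.47. A total of 3843 genes were called, 2264 higher and 1579 lower. With library totals alone the share of higher calls moved from 58.9% to 85.3%. Without G2 replicate 1 the count was 1970, with only the libraries compared 2510, with the 7 libraries without NA titles 2235, and with a term for title letters 386. Without G2 replicate 1 the fold changes had a median of 0.936 times their size, with the 7 libraries 1.05 and with title letters 1.16, and the median SE went from 0.204 to 0.242, 0.24 and 0.346.

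The calls of G1 and G2 against Control shared 1753 higher and 1268 lower genes, with 19 opposite. Independent lists of these lengths would share 441 and 282.1. Unchanged groups simulated against the same controls shared 0 and 0 on average over 20 simulations. With no gene changed almost none passes the threshold, so this count was nearly fixed in advance and is no benchmark for shared calls. Across genes, which are not independent replicates, the correlation of the fold changes was 0.751 (0.394 in the simulation) and the covariance 0.971 (0.0952 in the simulation, a difference of 0.876). With separate reference libraries, G1 against Control and G2 against wild type (single mutant) gave a correlation of 0.648 and a covariance of 0.884, and the opposite assignment 0.693 and 0.910.

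The last comparison set G2 against G1 (2 against 2 libraries). Cell cycle genes were lower in G2: 28 of 38 fell, 0 rose and 10 were not called (36 and 0 adjusted over the list alone). Rrm2, a subunit of ribonucleotide reductase, went from 52.5 ± 3.13 CPM in G1 to 16.2 ± 2.25 in G2 (-1.69 ± 0.15), and Anln, a cytokinesis protein, fell with -1.77 ± 0.25. Of 40 tubular injury genes 11 fell and 29 were not called (22 adjusted over the list alone), with Krt20 going from 169 ± 6.83 to 14.8 ± 1.82 CPM (-3.52 ± 0.57). Lcn2 (-0.83 ± 0.33) and Havcr1 (-1.64 ± 0.47) were not called. Of 26 endothelial genes 11 rose and 1 fell (20 and 2 adjusted over the list alone), among them the receptor gene Tie1 (1.26 ± 0.23) and the transcription factor gene Erg (1.45 ± 0.28). Of 43 matrix genes 10 rose and 1 fell (22 and 4 adjusted over the list alone), among them Col12a1 (1.79 ± 0.22) and Col15a1 (1.80 ± 0.26). Male-biased genes rose in 8 of 18 (14 adjusted over the list alone), with Slc7a13 from 14 ± 10.9 CPM in G1 to 399 ± 109 in G2. G1 replicate 2, which lacked Y-linked transcripts and held Xist, had 6.25 CPM of Slc7a13 and G1 replicate 1 had 21.7. Without G1 replicate 2, 1 of the 18 was called (Slc7a13, 4.15), and the list's median went from 2.14 to 1.59 (camera adjusted p = 2.18e-16). Of 8 erythrocyte genes 5 rose (5 adjusted over the list alone), with Hbb-bs from 5.86 ± 0.62 to 69.2 ± 36.9 CPM. Ren1, which encodes renin, fell from 285 ± 5.25 to 49.2 ± 6.56 CPM, against 92.4 ± 28 in Control. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.00286 for Rrm2, 0.0147 for Krt20, 0.00609 for Slc7a13, 0.0106 for Hbb-bs and 0.0226 for Ren1. Camera called 16 lists, 10 upward and 6 downward, and 0 with an estimated correlation. Camera adjusted p were 1.69e-33 for cell cycle, 6.29e-17 for tubular injury, 1.79e-10 for endothelium, 2.94e-07 for matrix, 6.29e-17 for male-biased genes and 3.46e-10 for erythrocytes. With an estimated correlation the camera adjusted p were, in the same order, 0.115, 0.115, 0.432, 0.424, 0.115 and 0.15.

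In G2 against G1 a total of 1198 genes were called, 684 higher and 514 lower, of which 495 and 262 by more than 2-fold. Of the genes also called in the mean of G1 and G2 against Control, 461 had risen there, 384 of them with the higher level in G1, and 402 had fallen, 377 of them with the lower level in G1. The count moved with single libraries: it was 84 without G1 replicate 1, 22 without G1 replicate 2, 778 without G2 replicate 1, 191 without G2 replicate 2, and 745 without wild type replicate 1 or without Control replicate 1. The fold changes of the 1198 genes moved less. Without G1 replicate 1 or 2 their median was 1.01 or 0.994 times that with all libraries, and without G2 replicate 1 or 2 it was 1.01 or 0.981 (1197 genes in the last), with every gene in the same direction. These genes were picked with the same libraries, so the ratios and directions are no independent check of the difference. The median SE rose from 0.244 to 0.308, 0.305, 0.285 and 0.284, and to 0.249 and 0.246 without wild type replicate 1 and Control replicate 1. A term for Y-linked transcripts marks G1 replicate 2 alone, so it acts as leaving that library out and is no separate check. With a term for Y-linked transcripts, which G1 replicate 2 lacked, 32 genes were called, at 0.993 times the size and a median SE of 0.304. With a term for title letters 1 gene was called and 0 of the 1198 remained, at 0.964 times the size and a median SE of 0.365; no title letters occur in both G1 and G2 libraries.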

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

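The tests weighed in this part, on the scaling of the libraries, on the G1 library without Y-linked transcripts and on the title letters, were chosen after the result was seen. What singled out the values of this part is a tested difference between the groups G1 and G2 (2 against 2 libraries), in edgeR's quasi-likelihood test. No group held 4 libraries or more, so no search for a library far from the rest of its group was made.

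A total of 1198 genes differed between G2 and G1. Among the largest differences, the glucuronosyltransferase exon Ugt1a2 stood lower in G2 by -5.25 ± 1.13 (log2 fold change ± SE), with reads that its family can share, as did the predicted genes Gm6505 (-4.36 ± 0.80) and Gm10639 (-4.30 ± 0.87). Also lower in G2 were the transporter-like ATPase gene Atp13a4 at -3.55 ± 0.53, the potassium channel partner gene Kcnip2 at -3.39 ± 0.76, the thyroxine carrier gene Serpina7 at -3.26 ± 0.61, the chemokine gene Cxcl1 at -3.24 ± 0.72, the chromatin protein gene Hmga2 at -3.17 ± 0.52 and Krt20 at -3.52 ± 0.57. Xist differed by -9.01 ± 2.14, from 1 G1 library. Higher in G2 were Hrg, with 0 counts in G1 (fitted log2 value 7.83, at least 22.7-fold against 3 counts), and Gm25682 (fitted log2 value 5.54, ratio 47.9 with a 95% counting interval of 16 to 235). The hormone gene Cck stood at 5.43 ± 0.62, the apolipoprotein gene Apoa2 at 5.13 ± 1.23, the organic anion transporter genes Slc22a28 and Slc22a30 at 5.07 ± 0.75 and 5.09 ± 0.69, and Mpped1 at 4.96 ± 0.59. The predicted genes Gm37194 and Gm4208 were at 4.60 ± 0.41 and 4.41 ± 1.05.

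By gene group, the male-biased genes Slc7a13 and Cyp7b1 were higher in G2 by 4.83 ± 0.55 and 4.25 ± 0.47. Without G1 replicate 2, the library that lacked Y-linked transcripts and held Xist, they stood at 4.15 ± 0.39 and 4.04 ± 0.67, and the calls of Cyp7b1 and, on the same list, of Slc22a28 (4.47 ± 0.94) and Slc22a30 (4.31 ± 0.62) were lost. The cell cycle genes Rrm2 and Anln were lower by -1.69 ± 0.15 and -1.77 ± 0.25, the transcription factor gene Fosl1 by -2.34 ± 0.36 and Mlkl by -1.74 ± 0.35. The matrix genes Col12a1, Col15a1 and Fbln1 were higher by 1.79 ± 0.22, 1.80 ± 0.26 and 1.90 ± 0.31, and the endothelial genes Erg and Tie1 by 1.45 ± 0.28 and 1.26 ± 0.23. The erythroid genes Hbb-bs and Alas2 were higher by 3.56 ± 0.48 and 2.84 ± 0.43 and the pericyte gene Rgs5 by 1.59 ± 0.22, while Ren1 was lower by -2.53 ± 0.48.

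The pattern to weigh is that most of these differences place G1 farther from Control than G2, as in 384 of the 461 genes that rose with the risk alleles and also differed between them. The scaling of the libraries is argued against as the whole cause of the differences, since a scaling shift moves all genes one way and 34.6% of the genes called by more than 2-fold lay in the rarer direction. The G1 library without Y-linked transcripts stays open: over the 6653 genes called for the risk alleles against Control, G1 lay farther from Control than G2 by a median log2 distance of 0.268, and of 0.235 without that library, where the fold changes of the 1198 genes had a median of 0.994 times their size, but these genes were picked with it and 1 G1 library remains. The title letters stay open as well. G1 and G2 libraries share none, and only single wild type (single mutant) libraries link their letters. A term for title letters therefore separates them from the alleles only with low precision. With that term 1 gene was called and 0 of the 1198 remained. The fold changes of the 1198 genes were then at 0.964 times their size, and the median SE went from 0.244 to 0.365. A difference between the alleles, in the stage of disease or in the age of the mice may also account for the pattern, and none of these was tested.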

How the results depend on the processing

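Scaling by library totals alone, a term for the 3 libraries with NA titles, and a fit of the 7 other libraries were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because replicate numbers followed accession order and the labels gave no number that groups shared.

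In the comparison of the risk alleles with Control, the named genes kept direction and side of the threshold in 2587 of 2763 values under the alternatives, and against wild type (single mutant) in 2769 of 2829. The numbers were 2543 of 2702 for G1 against Control, 2270 of 2495 for G2 against Control, 1616 of 2161 for G2 against G1, where 489 lost the call, and 2097 of 2158 for wild type (single mutant) against Control, where 14 gained it. Most named genes were picked by size or p-value in these same libraries, so these shares are no independent check. In wild type (single mutant) against Control no gene was called in the main test, so none could lose a call. Where a number of calls moved by over 1.5 times the cause was not tested, unless fewer libraries or lost degrees of freedom are named. The term for Y-linked transcripts marks G1 replicate 2 alone, so it acts as 1 library fewer. With a term for Y-linked transcripts 3390 genes were called in G1 against Control and 32 in G2 against G1, with fold changes at a median of 0.967 and 0.993 times their size and median SEs up from 0.198 to 0.255 and from 0.244 to 0.304. A term for title letters takes 3 degrees of freedom and is nearly aligned with the groups: it left 1811 genes for the risk alleles against Control, 1449 for G1, 386 for G2, 1 for G2 against G1 (Alb, with 0 of the 1198 remaining), and 3 for wild type (single mutant) against Control (C1s1, Gm1821 and C1rb). Against wild type (single mutant) the risk alleles had 6254, of which 5553 were shared with the 7120. A term for NA titles gave 1988 in G2 against G1 and 1 in wild type (single mutant) against Control (Cebpb). The 7 libraries with other titles gave 4216 for the risk alleles against Control, of which 3669 were shared with all 10, 2235 for G2 against Control, of which 1786 were shared, and 1 in wild type (single mutant) against Control (Rps3a3). DESeq2 called 2499 genes in G2 against G1 and 14 in wild type (single mutant) against Control. Without a low-count filter 4 were called there (Nr4a1, Kirrel2, Egr1 and Iglv2). With only the libraries compared, G2 against Control had 2510. The genes given in parentheses, where not named before, were chosen after their values were seen.

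Camera with an estimated correlation called 1 list for the risk alleles against Control, 1 against wild type (single mutant), 1 in wild type (single mutant) against Control and 0 in G2 against G1, and fry called 0 in wild type (single mutant) against Control. In sign, 3 values of named genes turned with a call on either side. Map1lc3b, a gene of autophagosomes, had a log2 fold change of 0.235 against Control and 0.25 against wild type (single mutant) with library totals alone, a scaling that moves every gene by one shift per library. Ighv7-3 in G1 against Control was at 0.596 with a term for title letters, and the cause was not tested.

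Leaving out each library in turn gave 4681 to 6883 genes for the risk alleles against Control, 5214 to 7067 against wild type (single mutant), 0 to 2 for wild type (single mutant) against Control, 3397 to 6912 for G1 against Control, 1970 to 4116 for G2 against Control and 22 to 1441 for G2 against G1. The 2 genes without Control replicate 1 were Nr4a1 and Rps3a3, and without Control replicate 3 Kirrel2 was called. Counts moved by over 1.5 times without G1 replicate 1 (4113 in G1 against Control, 84 in G2 against G1), G1 replicate 2 (3397 and 22), G2 replicate 1 (1970 in G2 against Control, 778 in G2 against G1), G2 replicate 2 (191 in G2 against G1), and without wild type replicate 1 or Control replicate 1 (745 each in G2 against G1). A group left with 1 library is assumed to vary as the others do. Depth sets the limit for genes near 3 counts, 0.0862 to 0.109 CPM.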

Other observations

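The tests of Kirrel2 and of the libraries with NA titles were chosen after the results were seen, and those on splits of the libraries before. Among the 6 reference libraries (Control and wild type (single mutant)), 3 have the letters NA, and not NAP, before the number in their titles (wild type replicate 3 and Control replicates 1 and 2), and 461 of 16262 genes differed between these and the other 3 (187 higher, 274 lower). Many of the largest differences were in immunoglobulin genes: of 76 tested 15 were higher and 0 lower, among them the constant region genes Ighg1 (log2 fold change 7.93), Ighg2c (5.81), Ighg3 (4.96) and Ighg2b (4.68) and the segments Igkv4-55 (5.78) and Igkv8-24 (5.03), whose reads copies can share. Hdc, the histamine-forming enzyme, was higher by 5.46 and Cyp2d12 by 4.12. Of 19 clock genes 6 were called. Arntl, which encodes the clock activator BMAL1, was higher in them by 3.27 ± 0.34 (log2 fold change ± SE) and its relative Npas2 by 3.94, while the clock output genes Per3, Tef, Nr1d2 and Ciart were lower by -1.67, -1.14, -1.23 and -2.85. Dbp, another output gene, was at -2.82 with an adjusted p of 0.0588 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

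The source of this split was not tested, and the labels state no time of day, batch or litter. The split is argued against as the whole source of the changes with the risk alleles, because without those 3 libraries 4216 genes were called against Control, where 1 Control library remains, and 6591 against wild type (single mutant), where 2 remain. For immunoglobulin genes it stays open: 65 of 112 fell against Control with all libraries, 27 with a term for NA titles, and 35 of 82 without those libraries. No biological explanation was tested.

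Kirrel2 was at 0.171, 0.256 and 0.204 CPM in the wild type (single mutant) libraries, 5.76, 9.02 and 2.19 in Control and 2.96 to 5.41 with the risk alleles. A lower podocyte content of the wild type (single mutant) libraries is argued against, since their podocyte list had a median log2 fold change of 0.184 against Control. The split by NA titles is argued against as well. Among libraries with NA titles the lowest Control was 28.2 times the highest wild type (single mutant) value, and among the others 8.56 times. The others pool different title letters, so this does not compare libraries within each kind of letters. Kirrel2 (chromosome 7, 30447534 to 30457690, GRCm38) lies on the minus strand, and its start is 624 bases from the start of Nphs1 on the plus strand, whose promoter is a known driver for podocyte transgenes, so Kirrel2 sequence carried by a transgene, or an altered locus, may account for the pattern. That stays open, because the transgene sequence was not used here and a difference made by the genotype itself was not tested.

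For the risk alleles against Control, 1 of 35 splits of the 7 libraries, the real one, gave as many genes. It gave 4537 with 2 groups fitted, and the highest other split gave 2. Against wild type (single mutant) it was again 1 of 35, the real one (5063, highest other 1). A random grouping is argued against by this share, the lowest that 35 splits can give, but is not excluded. Every other split mixes both groups, which widens the spread within them, so the gap in counts adds no support. The splits also cannot tell the genotype from anything else that follows the groups, such as title letters. For wild type (single mutant) against Control 10 splits are too few for a share under 0.05: all 10 gave at least the real 0, and the highest other gave 461. That split was the one by NA titles, which points to a structure of the samples.

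Values outside the comparisons were those of single libraries. Ttr, a marker of the choroid plexus and liver, was at 114 to 400 CPM in both G1 libraries, G2 replicate 1 and wild type replicates 1 and 2, and at 1.34 to 3.17 in the other 5. Rpsa-ps10, a ribosomal protein pseudogene that can share reads with its parent, was at 57.4 to 217 CPM in the same 5 libraries and at 2.28 to 3.09 in the rest. Both genes, like those of the clock split, were chosen after their values were seen.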
